A study of Mus musculus with 8 samples.

How the data were processed

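RNA-seq was done on sorted mouse muscle stem cells, 5 freshly isolated libraries and 3 libraries of cells cultured for 48 h. Per the labels' protocols, cells came from hindlimb muscle of 8 to 12 week old C57BL/6 females, and the growth medium held 20% fetal bovine serum with equal parts of a low-glucose medium and F-10. RNA was isolated with a Qiagen micro column kit, amplified as cDNA with NuGEN Ovation and built into Illumina libraries, per the labels' protocols. These kits add no molecular identifier that the labels mention, so intervals and floors cover counting error only. Per the submitters' processing notes, STAR, RSEM and the mouse build mm10 were used. Their versions and the annotation release are not given in the sources used here.

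The authors deposited 1 table of expected counts per gene, as RSEM estimates them, with 1 column per library and 45798 lines. Of the values above 0, 50.1% were not whole numbers, and all were rounded to whole numbers before testing. RSEM divides reads that fit several genes among them, so genes with near-identical copies are uncertain. The 92 lines of ERCC spike-in sequences, of which 26 held counts and which summed to 40.9 counts over all libraries, were left out, and 45706 lines were used. Of these, 2423 had no gene identifier, with 0.385 to 0.568% of counts per library, and they stayed in the tests under their symbol. A symbol already used stood on 1188 lines, and the line with an identifier and the most counts stood for such a symbol in the gene lists. Identifiers matched GENCODE M21, an annotation of mm10 (GRCm38), for 98.8% (42782), and coordinates are from that annotation. Group and run came from the labels, and all 8 columns carried the names in the labels.

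Genes were kept by edgeR's filterByExpr with its default settings, which left 19054 and left out 0.0984 to 0.665% of counts per library. Counts were scaled by TMM factors (0.790 to 1.18), and levels are CPM of the scaled library size. The main test was the edgeR 4.0.16 quasi-likelihood test in R 4.3.3 with sequencing run and culture as terms and Benjamini-Hochberg adjustment at 0.05, with 5 residual degrees of freedom. No cultured library was in run 1, so the culture coefficient compares cultured libraries with the fresh libraries of run 2, and the run-1 fresh libraries add to the estimate of the spread. The run coefficient of the same model compared fresh libraries of run 2 with those of run 1. Fold changes are log2, from the edgeR fit with its default prior count, so they are little shrunk for genes near 0 counts. A prior count of 2 was used only for log2 CPM. Standard errors are approximate, from the fold change and the test statistic. For a gene at 0 in a whole group, the fold is a lower bound against 3 counts over that group's run-2 libraries, which is 0.0517 CPM for cultured and 0.0962 CPM for fresh cells. For 1 to 3 counts, the ratio of run-2 means is given with a 95% counting interval. Values without a library are given where they moved by more than 1.5 times, for bounds and ratios only when that library held counts of the gene. For genes called in culture, settings that ended the call are named with the gene. Left out of this are the test against a log2 fold change of 1 and those chosen later that leave out libraries. The log2 fold change stands in brackets where it moved as far, but not for most genes given as bounds or ratios. The replicate block sets cultured libraries against run-1 fresh libraries.

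Gene lists were 28 lists of functions and 8 lists of cell type markers, of which 35 had at least 5 tested genes. They were tested with camera in limma 3.58.1 on log2 CPM with an inter-gene correlation of 0.01, and again with an estimated correlation, with adjustment over all lists. The limma function fry was run beside it and asks only whether the genes of a set move on balance one way, without a comparison with other genes. Calls of list members are given over all genes tested and adjusted over the list alone. Some genes are in more than one list, such as Dcn, Lum and Col3a1 in the matrix and fibro-adipogenic lists and Des in the myogenic and pericyte lists.

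The genes named are the 10 called genes with the largest fold change in each direction with a mean of at least 10 CPM and cultured libraries on one side of all fresh ones, 21 fixed genes, and in each list up to 4 called genes with the largest fold change and at least 10 CPM, or the 2 most abundant where fewer than 2 were called. For the runs, up to 5 per direction were allowed under the first of these criteria, and 4 and 4 passed. Predicted genes, small RNAs, histone and ribosomal protein genes and pseudogenes were passed over in both. Some genes that the rule takes are not reported here. Groups, the main test, the gene lists, this rule and most alternatives were set before the data were examined. Genes that complete a count of 5 or fewer, and those of the lists added later, were chosen after their values were seen. Alternatives set in advance were RLE factors, no scaling, no filter on low counts, a mean of at least 10 CPM, DESeq2 1.42.0, limma-voom, leaving out abundant and mitochondrial genes, no run term, run 2 alone, run-1 fresh libraries as the control, the replicate number as a block, a test against a log2 fold change of 1, the fresh libraries alone and leaving out each library. Chosen after the data were seen were fresh replicate 1 alone as the control, run 2 without cultured replicate 1, and removal of trends with GC content and transcript length, which were known for 95.9% of tested genes.

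The scripts' statistics were tested on simulated data for the comparison of cultured with fresh cells, with 19054 genes and 50 changed at each size. At adjusted p of 0.05, 0, 8, 22 and 36% of genes were recovered at a log2 fold change of 1, 2, 3 and 4, with 1 false call among 34 calls. At the unadjusted p that the real calls reached (0.0134), 16, 46, 66 and 74% were recovered and 1.08% of unchanged genes passed. Median fitted fold changes were 0.89, 2.01, 3.18 and 4.00. The changed genes were drawn from those with a mean of at least 1 CPM, and no difference between runs was simulated. The recovery rates therefore do not cover rarer genes or a run difference. Camera called the 1 changed list and 0 of 34 unchanged lists. Genes were drawn independently, and the changed list held only genes raised by a log2 fold change of at least 2. The simulation therefore cannot show how camera behaves when the genes of a list are correlated.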

Results

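Gene expression was measured by RNA-seq in muscle stem cells, the resident progenitors of skeletal muscle, from hindlimb muscles of female C57BL/6 mice aged 8 to 12 weeks. The cells were sorted for α7-integrin and CD34, and cells carrying CD45, CD11b, Sca1 or CD31, surface proteins of blood, fibro-adipogenic and endothelial cells, were left out. Of the 8 libraries, 5 came from freshly sorted cells and 3 from cells cultured for 48 h on a hydrogel of 12 kPa. Fresh replicates 1 to 3 were sequenced in one run (run 1), and fresh replicates 4 and 5 shared a lane with the 3 cultured libraries (run 2). Total counts were 16248271, 13919440, 16595097, 20055185 and 18276317 in fresh replicates 1 to 5. They were 20068154, 17162106 and 16654631 in cultured replicates 1 to 3. At least 1 count was seen for 34008, 32710 and 34689 genes in the run-1 fresh libraries, 20480 and 20898 in the run-2 fresh libraries, and 15415, 17852 and 17806 in the cultured libraries. Mitochondrial ribosomal RNA took 5.25, 5.74, 10.5, 26.5 and 23.2% of counts in the fresh libraries and 18.4, 11.7 and 11.1% in the cultured ones. No pair of libraries agreed within sampling noise, so each counted as 1 sample. Whether the libraries came from separate animals or cultures is not given in the sources used here, so p-values measure only the spread between these samples, which may be technical.

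The comparison of cultured with fresh cells asked how the transcriptome of muscle stem cells, with its metabolic and chromatin enzymes, differs after 48 h outside the animal. In culture, transcripts of quiescent stem cells fell and those of cell division rose. Pax7, the transcription factor that marks muscle stem cells, fell from 1159.9 ± 281 to 77.4 ± 22.2 CPM (mean ± SD, n = 5 and 3 here and for all levels of fresh and cultured cells), a log2 fold change of -4.05 ± 0.37 (± SE; adjusted p = 0.000253, edgeR quasi-likelihood test). Calcr, the calcitonin receptor of quiescent stem cells, fell from 176 ± 122 to 1.45 ± 1.65 CPM (-7.72 ± 1.13; adjusted p = 0.00210). Spry1, an inhibitor of receptor tyrosine kinase signalling, fell from 285 ± 63.2 to 14.0 ± 11.4 CPM (-4.43 ± 0.61; adjusted p = 0.00162). Ccnd1, the cyclin D1 gene of G1 phase, rose from 95.9 ± 58.1 to 791 ± 109 CPM (3.87 ± 0.50; adjusted p = 0.00126). Mki67, a marker of cycling cells, rose from 27.2 ± 18.0 to 627 ± 228 CPM (4.02 ± 0.86; adjusted p = 0.00971). Its adjusted p was 0.0775 without fresh replicate 4 and 0.0747 without fresh replicate 5. Of the myogenic factors, Myf5 fell from 278 ± 35.7 to 70.6 ± 3.39 CPM (-2.12 ± 0.21; adjusted p = 0.000331). Myod1, the factor of activated myoblasts, rose from 76.5 ± 11.5 to 209.7 ± 49.3 CPM (1.63 ± 0.29; adjusted p = 0.00506). Myog, the differentiation factor, was low throughout, at 2.34 ± 1.06 CPM in fresh and 0.0170 ± 0.0294 CPM in cultured cells. Its level in the run-2 fresh libraries exceeded that in the cultured ones by a ratio of 189.8 (counting interval 33.3 to 7571) (adjusted p = 0.00635). Both surface proteins of the sort did not pass the test, with Cd34 at 239 ± 65.4 and 171 ± 34.4 CPM (adjusted p = 0.638) and Itga7 at 71.0 ± 19.2 and 83.5 ± 30.1 CPM (adjusted p = 0.241) in fresh and cultured cells. Pax7 (ENSMUSG00000028736) lies on chromosome 4, 139737062 to 139833528, in the GENCODE M21 annotation of mm10. Calcr had a log2 fold change of -7.08 without cultured replicate 1 and -9.03 without cultured replicate 2, and Spry1 of -5.28 without cultured replicate 1. The lower group kept no count of Myog without cultured replicate 3 (at least 41.9-fold). Myog lost the call with the replicate block.

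Of 19054 genes tested, 5122 passed a Benjamini-Hochberg adjusted p of 0.05 in edgeR's quasi-likelihood test with run as a term, 1691 higher and 3431 lower in cultured cells. A log2 fold change of at least 1 was met by 1635 of the higher and 3384 of the lower genes. In 4760 of the 5122 all cultured libraries lay on one side of all fresh ones, as did 39.9% of all tested genes, against 3.57% by chance. Without scaling factors the split was 2452 higher and 2857 lower, and single fold changes moved by a median of 0.41 on the log2 scale. With run in the model, fold changes rest on fresh replicates 4 and 5, and the count was 3402 without fresh replicate 4, 3337 without fresh replicate 5 and 2780 with run 2 alone.

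**Figure D1:**
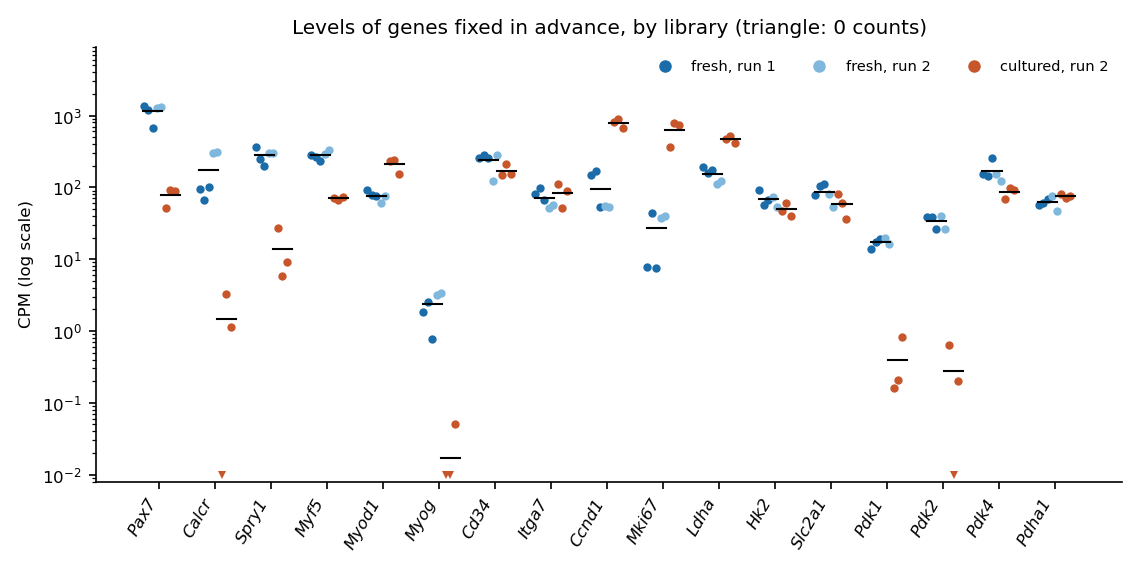
Expression (CPM, log axis) of 17 of the genes fixed in advance, 1 point per library, in fresh cells of run 1, fresh cells of run 2 and cultured cells, with bars at the group means and triangles for libraries with 0 counts. Pax7 fell from 1159.9 ± 281 CPM (mean ± SD) in fresh cells to 77.4 ± 22.2 CPM in culture, and Ccnd1 rose from 95.9 ± 58.1 to 791 ± 109 CPM.

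Among the genes with the largest rise, Hmga2, an architectural chromatin protein of growing cells, rose from 2.43 ± 1.88 to 827 ± 179 CPM (9.21 ± 1.17; adjusted p = 0.00113), a fold change of 8.36 without fresh replicate 4 and 12.06 without fresh replicate 5. Sema7a, a membrane-anchored semaphorin, rose from 2.17 ± 1.92 to 90.1 ± 14.5 CPM (9.07 ± 0.58; adjusted p = 6.04e-05), and Slc7a11, the cystine transporter, from 1.37 ± 1.30 to 80.6 ± 38.3 CPM (8.91 ± 0.87; adjusted p = 0.000338). Mcm10, a replication initiation factor, reached 63.5 ± 56.7 CPM in culture, a ratio of 981 (counting interval 271 to 8099) over run-2 fresh cells. E2f8, an E2F family repressor, reached 31.2 ± 22.1 CPM with a ratio of 488 (counting interval 135 to 4031). The ratios were 601 (counting interval 206 to 2918) for Lrp8, a lipoprotein receptor, and 615 (counting interval 170.0 to 5078) for Espl1, the separase that parts sister chromatids. Dntt, a template-independent DNA polymerase, had no count in run-2 fresh cells and 27.1 ± 29.0 CPM in culture, at least 278-fold higher. Zbtb9 was likewise at 0 there and at 45.8 ± 59.8 CPM in culture, at least 469-fold higher, with an adjusted p of 0.0186 that became 0.0896 and 0.0918 without fresh replicate 4 or 5. Against the run-1 fresh libraries alone the fold changes were smaller, 4.74 for Sema7a and 5.28 for Slc7a11, and each passed the test. Against fresh replicate 1 alone, of run 1, log2 fold changes were 4.64 for Lrp8, 4.27 for Espl1 and 5.735 for Mcm10. They were 5.81 for E2f8 and 7.26 for Dntt there. The main test gave 9.12, 9.09, 9.80, 8.77 and 11.87 for these genes in turn. The ratios and bounds here therefore describe run-2 fresh cells only. The bound was 110.2 without cultured replicate 1 for Dntt, and 118 without cultured replicate 1 for Zbtb9. The ratio was 485 without cultured replicate 1 for Mcm10, and 288 without cultured replicate 2 for E2f8, and 916 without fresh replicate 5 for Lrp8. The lower group kept no count of Mcm10 without fresh replicate 4 (at least 322-fold) and Espl1 without fresh replicate 5 (at least 208-fold). Zbtb9 lost the call with the replicate block, which sets cultured libraries against run-1 fresh libraries.

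Several of the genes with the largest fall had no count in culture. Abcc9, a subunit of ATP-sensitive potassium channels, averaged 168 ± 86.0 CPM in fresh cells and had no count in culture, at least 2972-fold lower against a floor of 3 counts over the 3 cultured libraries. The potassium channel genes Kcna2 (87.0 ± 45.9 CPM in fresh cells) and Kcne4 (86.0 ± 27.6 CPM) were at least 2095-fold and 1717-fold lower, and Steap4, a metalloreductase, at least 2093-fold lower from 113 ± 52.8 CPM. The tight junction gene Cldn1, Hr, Islr, Pdgfrl and Gucy1a3, a subunit of the nitric oxide receptor, were at least 1605, 1140.3, 1101, 1096 and 1033-fold lower. Rgs5, a regulator of G protein signalling abundant in pericytes, fell from 953 ± 504 to 0.119 ± 0.164 CPM (-12.85 ± 1.29; adjusted p = 0.000391). Over these 10 genes the edgeR adjusted p lay between 0.000105 for Hr and 0.00186 for Gucy1a3. In fresh replicate 1, Rgs5 was lower than the mean of fresh replicates 2 and 3 by a log2 ratio of -3.29, Abcc9 by -2.56, Kcna2 by -3.03 and Steap4 by -2.29, while Hr stood at 0.18 and Pdgfrl at 0.70. Where fresh replicate 1 was low, loss of other cells' RNA and a fall in the stem cells cannot be told apart. Abcc9 (ENSMUSG00000030249) lies on chromosome 6, 142587862 to 142702315, Rgs5 (ENSMUSG00000026678) on chromosome 1, 169655501 to 169695813 and Hmga2 (ENSMUSG00000056758) on chromosome 10, 120361275 to 120476469, all protein coding. Rgs5 had a log2 fold change of -12.24 without cultured replicate 1 and -14.78 without cultured replicate 3.

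Among 29 quiescence genes, 22 fell, 1 rose and 6 did not pass the test. The 1 that rose, named after its value was seen, was the heparan sulfate proteoglycan gene Sdc3 (1.57 ± 0.37; adjusted p = 0.0134, 0.0870 without fresh replicate 4 and 0.0678 without fresh replicate 5). Heyl, a Notch effector, fell from 690.0 ± 121 to 1.24 ± 1.76 CPM (-9.08 ± 1.13). Fgfr4, a fibroblast growth factor receptor of this lineage, fell from 438 ± 95.8 to 3.19 ± 1.74 CPM (-7.27 ± 0.49), and Chrdl2, a secreted BMP antagonist, from 369.9 ± 81.8 to 3.41 ± 3.24 CPM (-6.72 ± 0.75). Adjusted over the list alone, 23 were lower and 1 higher. The list median was -4.13 (camera adjusted p = 6.60e-07, 0.0202 with an estimated correlation), and its median log2 ratio of fresh replicate 1 to fresh replicates 2 and 3 was 0.10. Of 16 Notch pathway genes, 10 fell and none rose, and 11 were lower when adjusted over the list alone. Hey1 fell from 144 ± 36.8 to 1.90 ± 1.69 CPM (-6.37 ± 0.84) and the receptor Notch3 from 391 ± 84.1 to 15.1 ± 10.9 CPM (-4.61 ± 0.59). The Notch list passed camera (adjusted p = 0.00318) but had an adjusted p = 0.0816 with an estimated correlation, and 0.0786 against run-1 fresh cells alone. Heyl had a log2 fold change of -11.41 without cultured replicate 1, Chrdl2 of -7.84 without cultured replicate 3, and Hey1 of -7.18 without cultured replicate 1. Notch3 had a log2 fold change of -5.25 without cultured replicate 1.

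The 22 myogenic commitment genes went both ways, with 6 higher and 7 lower, and 8 and 8 adjusted over the list alone. Dok7, an adaptor of the neuromuscular synapse, rose from 0.949 ± 0.543 to 62.2 ± 25.5 CPM (6.91 ± 0.84), while Mef2c, a differentiation factor, fell from 20.5 ± 11.6 to 0.0849 ± 0.147 CPM (-7.18 ± 1.31; adjusted p = 0.0532 with run 2 alone). Its median of -0.25 was negative, but 0.18 without scaling factors and 0.22 with GC and length trends removed. Fry pointed down, while camera pointed up, and the list did not pass (adjusted p = 0.648, 0.761 with an estimated correlation). Dok7 had a log2 fold change of 7.92 without fresh replicate 4, and Mef2c of -6.58 without cultured replicate 1. Cultured cells kept no count of Mef2c without cultured replicate 3.

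Cell division genes rose together. Of 34 mitotic genes, 23 rose and none fell, and 31 were higher when adjusted over the list alone. Ttk, a spindle checkpoint kinase, rose from 0.949 ± 0.709 to 27.1 ± 11.4 CPM (7.08 ± 0.91), and Cdk1, the mitotic kinase, stood at 29.1 ± 13.7 CPM in culture, a ratio of 455 (counting interval 126 to 3761) over run-2 fresh cells. The list median was 4.06 (camera adjusted p = 1.18e-18, 0.0202 with an estimated correlation). Of 40 DNA replication genes, 25 rose and none fell, with 31 higher adjusted over the list alone. Uhrf1, which maintains DNA methylation at replication, rose from 0.982 ± 1.16 to 62.5 ± 29.9 CPM (7.30 ± 1.48) and Mcm2, a subunit of the replicative helicase, from 3.77 ± 2.91 to 74.2 ± 54.3 CPM (5.75 ± 0.99). Its median was 2.62 (camera adjusted p = 1.74e-17, 0.00715 with an estimated correlation). Among 19 cell cycle brakes, 9 fell and 3 rose (9 and 4 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.0948). Btg2, an antiproliferative gene, fell from 1255 ± 290.1 to 28.5 ± 6.20 CPM (-5.04 ± 0.24), and Sesn1, a stress-inducible regulator of growth, from 79.4 ± 7.97 to 0.890 ± 0.591 CPM (-6.49 ± 0.64). Rbl2, the retinoblastoma relative of resting cells, fell by 4.08 ± 0.44 on the log2 scale. The 3 that rose, named after their values were seen, were Cdkn1a, the p53 target that inhibits cyclin-dependent kinases (2.48 ± 0.34), Ccng1 (3.73 ± 0.35) and Trp53 (2.18 ± 0.27). Ttk had a log2 fold change of 7.68 without fresh replicate 5, Uhrf1 of 6.49 without fresh replicate 4 and 9.82 without fresh replicate 5, and Mcm2 of 4.97 without cultured replicate 2, 7.19 without fresh replicate 4 and 5.09 without fresh replicate 5. Cdk1 lost the call with the replicate block, at a log2 fold change of 5.12 against 8.67 in the main test.

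Glycolytic genes split. Ldha, which reduces pyruvate to lactate, rose from 153 ± 34.9 to 468 ± 51.8 CPM (2.00 ± 0.23; adjusted p = 0.000681), while the glucose transporter gene Slc2a1 (86.3 ± 23.5 and 59.0 ± 22.1 CPM; adjusted p = 0.770) and hexokinase Hk2 (68.7 ± 15.7 and 49.4 ± 10.6 CPM; adjusted p = 0.471) did not pass the test. Of 26 glycolysis genes, 10 rose and 4 fell, and 10 and 5 adjusted over the list alone. Eno1 rose from 50.2 ± 14.0 to 518 ± 59.0 CPM (3.72 ± 0.31), Pgam1 by 3.65 ± 0.38 and Pgk1 by 2.98 ± 0.37 on the log2 scale, and each has processed copies in the genome that share its reads. Pfkfb2, a bifunctional regulator of phosphofructokinase, fell from 23.3 ± 8.54 to 0.878 ± 0.127 CPM (-4.56 ± 0.66). The other genes that fell, named after their values were seen, were Eno2, at 0 in culture and at least 40.9-fold lower, Pfkp (-1.78 ± 0.36; adjusted p = 0.0519 without fresh replicate 5) and Pfkfb4 (adjusted p = 0.0488, and 0.0615 to 0.152 without fresh replicates 1, 2, 3, 4 and 5 and cultured replicate 2 in turn). The list had a median of 0.02 and a mean of -0.28, camera pointed up, and it did not pass (adjusted p = 0.103). Pfkfb2 had a log2 fold change of -3.36 without fresh replicate 4 and -5.18 without fresh replicate 5. The bound was 26.5 without fresh replicate 4 for Eno2. Eno2 lost the call with the replicate block, and Pfkp with GC and length trends removed (-1.13). Pfkfb4 lost the call against run-1 fresh libraries (-4.48), with the replicate block (-6.41), without scaling factors, with GC and length trends removed and with run 2 alone.

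The kinases that switch off pyruvate dehydrogenase fell in part. Pdk1 fell from 17.1 ± 2.27 to 0.393 ± 0.366 CPM (-5.48 ± 0.85; adjusted p = 0.00280) and Pdk2 from 34.03 ± 6.95 to 0.279 ± 0.323 CPM (-6.86 ± 1.05; adjusted p = 0.00261). Without 1 cultured library the fold changes lay between -6.55 (without replicate 3) and -5.05 (without replicate 1) for Pdk1 and between -8.18 (without replicate 1) and -6.29 (without replicate 2) for Pdk2. Pdk3 (3.50 ± 1.39 and 5.17 ± 3.47 CPM; adjusted p = 0.872), Pdk4 (166 ± 51.4 and 86.7 ± 15.5 CPM; adjusted p = 0.143) and Pdha1, the E1 subunit of the complex (61.5 ± 10.9 and 75.3 ± 4.39 CPM; adjusted p = 0.493), did not pass. Pdk4 was lower with no run term (-0.94; adjusted p = 0.0284), against run-1 fresh libraries (-1.03; 0.0331) and with GC and length trends removed (-0.90; 0.0431). Of 14 genes of the complex and its regulators 4 fell and 1 rose. The phosphatase gene Pdp1 fell by 2.65 ± 0.71 on the log2 scale (adjusted p = 0.0241, and 0.0711 without fresh replicate 4 and 0.0966 without fresh replicate 5) and the pyruvate carrier gene Mpc2, which also fell, had an adjusted p of 0.0422, and 0.0715 to 0.180 without fresh replicates 1, 2, 3, 4 and 5 and cultured replicate 2 in turn. Dlat, the acetyltransferase subunit, rose by 1.505 ± 0.36 and was named after its value was seen (adjusted p = 0.0159, and 0.0632 without fresh replicate 4 and 0.0994 without fresh replicate 5). Adjusted over the list alone 4 were lower and 2 higher, without scaling factors 3 and 2, and camera did not call the list (adjusted p = 0.682). Pdp1 had a log2 fold change of -3.47 without cultured replicate 1. Pdp1 and Dlat lost the call with the replicate block and with run 2 alone, and Mpc2 with no run term, against run-1 fresh libraries (-0.67), with the replicate block (-0.81), without scaling factors, with run 2 alone and with no filter.

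Of 18 TCA cycle genes 5 rose and none fell, the same number adjusted over the list alone, among them Mdh2 (66.8 ± 16.3 to 218 ± 30.6 CPM; 1.99 ± 0.29) and Sdhd (2.07 ± 0.40). Idh3a (adjusted p = 0.0755 without fresh replicate 4 and 0.0610 without fresh replicate 5), Cs (0.0726 without fresh replicate 5) and Dlst (0.105 without fresh replicate 5), the last named after its value was seen, passed in the full set of libraries, and camera gave an adjusted p = 0.00320, or 0.138 with an estimated correlation. Without scaling factors 8 rose. Of 52 oxidative phosphorylation genes 12 rose and none fell (11 adjusted over the list alone), and 40 did not pass. Without scaling factors 26 rose, and with GC and length trends removed 6 rose and 1 fell, the median 0.89 becoming 0.34. Cox5a, a cytochrome c oxidase subunit, rose from 8.41 ± 2.89 to 71.3 ± 9.998 CPM (2.66 ± 0.41). The camera adjusted p was 4.64e-08, and the adjusted p = 0.126 with an estimated correlation. Of 24 fatty acid oxidation genes, 4 fell and none rose, the same numbers adjusted over the list alone, and the list did not pass (adjusted p = 0.220). Without scaling factors 4 fell and 1 rose, and with the trends removed 6 and 1. Ppargc1a, a coactivator of mitochondrial biogenesis, fell from 16.7 ± 4.86 to 0.348 ± 0.267 CPM (-5.63 ± 0.88). The fatty acid transporter gene Cd36 was at 24.5 ± 13.4 CPM in fresh cells and 0 in culture, at least 454-fold lower. The lipase gene Lpl (adjusted p = 0.0113, and 0.0690 without fresh replicate 4) and Ehhadh, named after its value was seen (0.0283, and 0.0605 to 0.0931 without fresh replicate 5 and cultured replicates 1, 2 and 3 in turn), made up the rest. Cpt1a, which admits fatty acids to mitochondria, stood at 127 ± 21.9 and 119 ± 95.1 CPM (adjusted p = 0.990). Ppargc1a had a log2 fold change of -6.31 without cultured replicate 1. Sdhd and Dlst lost the call with the replicate block, and Idh3a with the replicate block (1.75). Cs lost the call with no run term (0.53), against run-1 fresh libraries (0.25) and with the replicate block (0.18), and Lpl against run-1 fresh libraries (-1.65) and with the replicate block (-2.02). Ehhadh lost the call with the replicate block and with no filter.

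Of 15 genes of acetyl-CoA supply and lipogenesis, 3 fell and none rose, also adjusted over the list alone, and camera did not call the list (adjusted p = 0.431). With GC and length trends removed, as without scaling factors, 3 fell and 3 rose. Those that fell in the main test were the desaturases Scd1 (316 ± 64.4 to 56.1 ± 22.5 CPM; -2.26 ± 0.34) and Scd2 (-2.22 ± 0.35) and the acetyl-CoA synthetase Acss2 (-4.47 ± 0.95; adjusted p = 0.0588 with run 2 alone). Acly, which makes cytosolic acetyl-CoA from citrate, stood at 47.2 ± 16.5 and 72.5 ± 22.5 CPM (adjusted p = 0.0917). It was higher without cultured replicate 1 (1.35; adjusted p = 0.0254), also within run 2 (0.0482), without scaling factors (0.0415) and with the trends removed (0.0334). Of 23 sterol synthesis genes 11 fell and none rose, with 14 lower adjusted over the list alone and 6 without scaling factors, including Cyp51 (135 ± 34.1 to 20.2 ± 2.64 CPM; -3.00 ± 0.29) and Fdft1 (-2.68 ± 0.49). The camera adjusted p was 0.00121, but the adjusted p = 0.207 with an estimated correlation. Acss2 had a log2 fold change of -5.67 without cultured replicate 3.

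Of 7 pentose phosphate genes 3 rose (4 adjusted over the list alone) and none fell, led by G6pdx, which feeds glucose into the pathway (19.8 ± 8.58 to 178 ± 34.1 CPM; 3.96 ± 0.44), and Pgd (3.09 ± 0.51), with Tkt at an adjusted p of 0.0123 (0.0843 without fresh replicate 4). Of 16 nucleotide synthesis genes 11 rose and none fell, also adjusted over the list alone, among them Atic (41.0 ± 12.0 to 267 ± 50.5 CPM; 3.07 ± 0.34), Cad (2.93 ± 0.37) and Nme1 (3.60 ± 0.68). Camera adjusted p was 0.00320 and 2.88e-08 for these lists, and each had an adjusted p = 0.0816 with an estimated correlation. Of 20 genes of serine and one-carbon metabolism and the amino acid response, 13 rose (15 adjusted over the list alone) and none fell. Mthfd2, a mitochondrial folate enzyme, rose from 5.58 ± 3.72 to 69.0 ± 38.5 CPM (4.94 ± 0.74), and Phgdh, the entry enzyme of serine synthesis, from 1.28 ± 0.744 to 31.9 ± 5.64 CPM (4.99 ± 0.82). Asns, the asparagine synthetase, rose from 2.50 ± 1.46 to 57.3 ± 1.74 CPM (5.19 ± 1.38; adjusted p = 0.0814 with run 2 alone). The list passed camera (adjusted p = 1.08e-08, 0.0202 with an estimated correlation). Ribosome biogenesis moved most completely, with 27 of 28 genes higher, none lower and the same counts adjusted over the list alone. Nop2, an RNA methyltransferase of the nucleolus, rose by 3.33 ± 0.43 and Wdr12 by 3.27 ± 0.35 on the log2 scale. The list had a camera adjusted p of 2.44e-16 and an adjusted p = 0.0816 with an estimated correlation. G6pdx had a log2 fold change of 4.69 without fresh replicate 4, Pgd of 3.97 without fresh replicate 5, and Nme1 of 5.08 without fresh replicate 4 and 2.91 without fresh replicate 5. Mthfd2 had a log2 fold change of 5.55 without fresh replicate 4, and Asns of 4.24 without fresh replicate 4. Run-2 fresh cells kept no count of Asns without fresh replicate 5. Tkt lost the call with the replicate block.

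**Figure D2:**
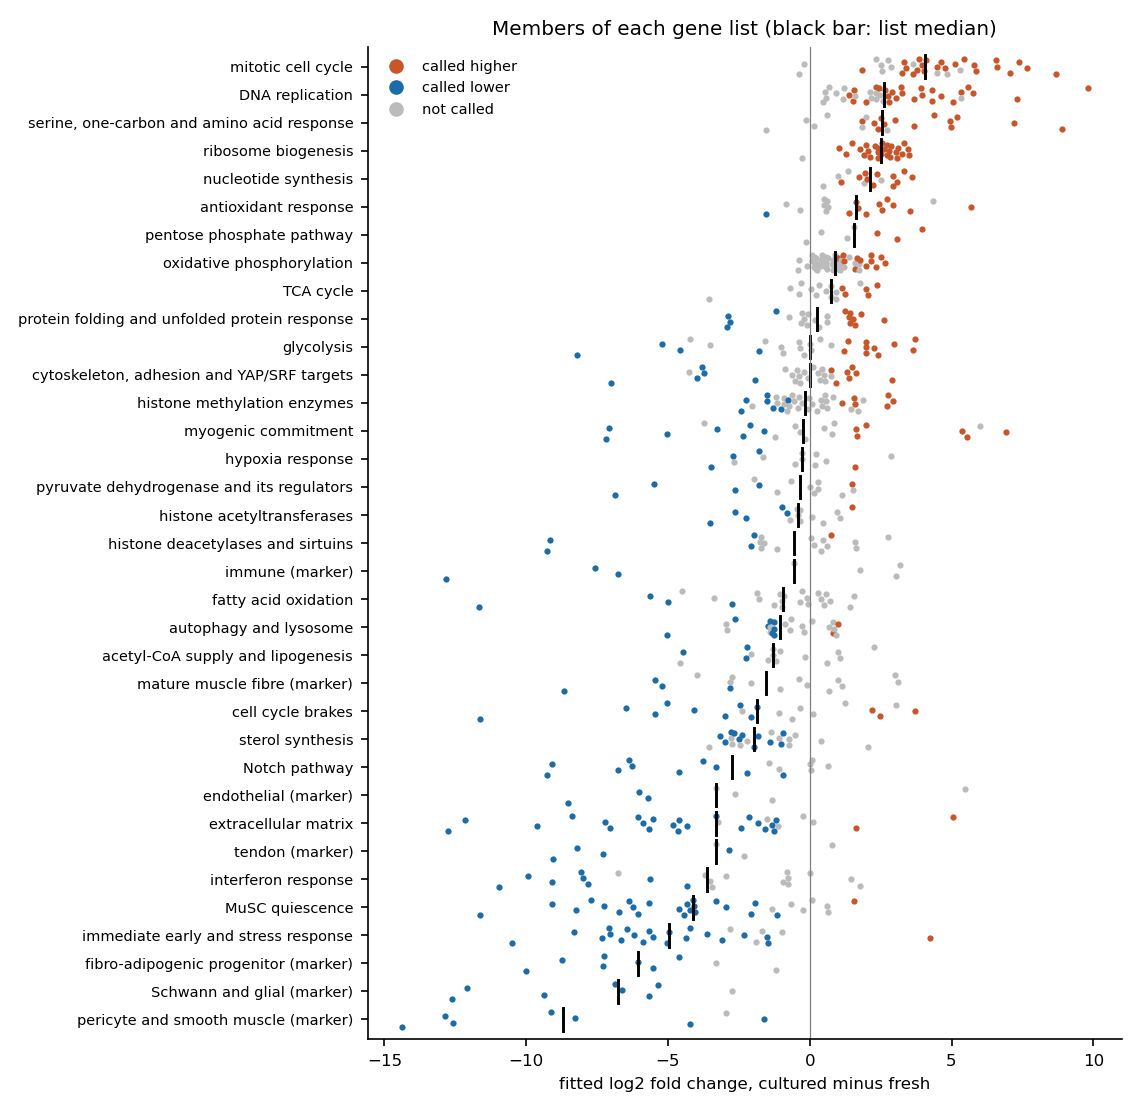
Log2 fold change of cultured over fresh cells (edgeR) for each tested member of the gene lists, 1 point per gene, with members called higher in orange, called lower in blue and not called in grey, and black bars at the list medians. Mitotic genes centre on 4.06 and ribosome biogenesis genes on 2.53, while quiescence genes centre on -4.13 and immediate early genes on -4.95.

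Chromatin-modifying enzymes moved in both directions, and none of their lists passed camera. Of 15 histone acetyltransferases 5 fell and 1 rose (6 and 2 adjusted over the list alone; camera adjusted p = 0.648). Without scaling factors 2 fell and 2 rose, and with GC and length trends removed 3 fell and 1 other than Hat1 rose, the median -0.41 becoming 0.03. Ncoa1, a nuclear receptor coactivator, fell from 527 ± 99.7 to 53.8 ± 23.6 CPM (-3.51 ± 0.36) and Kat6b from 191 ± 42.3 to 44.8 ± 12.4 CPM (-2.23 ± 0.33). Kat2b (adjusted p = 0.0359, and 0.0551 to 0.145 without fresh replicates 1, 2, 3, 4 and 5 and cultured replicate 3 in turn) and, named after their values were seen, Taf1 (0.0145, and 0.1002 without fresh replicate 5) and Ncoa3 (0.0425, and 0.0605 to 0.264 without fresh replicates 1, 2, 3, 4 and 5 and cultured replicates 1, 2 and 3 in turn) made up the rest of those that fell. The 1 that rose was Hat1 (1.49 ± 0.43; adjusted p = 0.0319), with an adjusted p of 0.0523 to 0.135 without fresh replicates 1, 4 and 5 and cultured replicates 2 and 3 in turn. Of 18 deacetylases and sirtuins 4 fell and 1 rose, also adjusted over the list alone (3 and 2 without scaling factors, 3 and 0 with the trends removed; camera adjusted p = 0.635). Sirt2, an NAD-dependent deacetylase, fell from 124 ± 21.9 to 26.2 ± 11.4 CPM (-2.07 ± 0.39; adjusted p = 0.00567, 0.0513 without fresh replicate 4). Hdac4 fell by 1.98 ± 0.44 on the log2 scale (adjusted p = 0.0114, 0.0712 without fresh replicate 5). Hdac9 and Hdac11, named after their values were seen, were at 0 in culture and at least 78.8 and 85.6-fold lower. Hdac2 was higher at an adjusted p of 0.0474, and 0.0735 to 0.190 without fresh replicates 1, 2, 3, 4 and 5 and cultured replicates 2 and 3 in turn. Sirt1, the sirtuin that deacetylates H4K16, stood at 38.1 ± 18.4 and 62.8 ± 26.2 CPM in fresh and cultured cells (adjusted p = 0.852). Of 38 histone methylation enzymes, 7 fell and 6 rose (9 and 8 adjusted over the list alone), with a median of -0.16, a mean of 0.01 with camera pointing up and fry down (camera adjusted p = 0.604). Without scaling factors 4 fell and 10 rose (median 0.20), and with the trends removed 4 fell and 8 rose (median 0.12). The H4K20 methyltransferase Setd8 rose from 40.3 ± 11.7 to 235 ± 51.2 CPM (2.93 ± 0.36) and the arginine methyltransferase Prmt5 by 2.73 ± 0.39, and Kmt2c, an H3K4 methyltransferase, fell from 469.6 ± 104 to 107 ± 43.4 CPM (-2.43 ± 0.33). The bound was 46.4 without fresh replicate 5 for Hdac9. Kat2b lost the call against run-1 fresh libraries (-2.05), with the replicate block, without scaling factors and with run 2 alone, and Taf1 with the replicate block, without scaling factors, with GC and length trends removed and with no filter. Ncoa3 lost the call with the replicate block, without scaling factors, with GC and length trends removed (-0.17), with run 2 alone and with no filter, and Hat1 with GC and length trends removed (0.85) and with no filter. Hdac4 lost the call without scaling factors and with GC and length trends removed (-1.24), and Hdac9 with the replicate block. Hdac2 lost the call with GC and length trends removed, with run 2 alone, with no filter, with RLE factors and with a mean of at least 10 CPM.

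Immediate early and stress genes fell, 20 of 25 lower and 1 higher, or 22 and 1 adjusted over the list alone. Fos fell from 2640.2 ± 996 to 11.2 ± 4.45 CPM (-8.31 ± 0.50) and Nr4a1, an orphan nuclear receptor induced by stimulation, from 861 ± 159 to 5.49 ± 4.66 CPM (-7.34 ± 0.70). The heat shock gene Hspa1b fell by 7.04 ± 0.60, though it shares reads with its near-identical copy Hspa1a. Egr1 took 1.82 ± 0.358% of all counts in fresh and 0.0523 ± 0.0265% in cultured cells. The fresh cells had been isolated and sorted, and no cells left in the muscle were measured. A raised level in fresh cells and a fall due to culture therefore cannot be told apart. The gene that rose, named after its value was seen, was Fosl1, an AP-1 subunit (53.3 ± 22.2 to 631 ± 192 CPM; 4.26 ± 0.42). The list passed camera (adjusted p = 1.49e-09, 0.0480 with an estimated correlation). Nr4a1 had a log2 fold change of -8.24 without cultured replicate 2, and Hspa1b of -7.72 without cultured replicate 2.

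Antioxidant genes rose, 10 of 19 higher and 1 lower, or 12 and 1 adjusted over the list alone. Hmox1, which breaks down heme, rose from 20.6 ± 5.96 to 887 ± 85.0 CPM (5.70 ± 0.42; 5.25 without fresh replicate 5 and 6.46 without fresh replicate 4). Gclm, which sets the rate of glutathione synthesis, rose by 3.53 ± 0.43 and glutathione reductase Gsr by 2.92 ± 0.44. The gene that fell, named after its value was seen, was the glutathione transferase Gstm1 (-1.55 ± 0.24). The list passed camera (adjusted p = 2.35e-06, 0.0202 with an estimated correlation).

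Of 22 protein folding genes 8 rose and 4 fell, the same adjusted over the list alone, and the list did not pass (adjusted p = 0.0594, or 0.0197 without scaling factors). Hspa9, a mitochondrial chaperone, rose from 139.5 ± 18.7 to 759 ± 119.7 CPM (2.62 ± 0.24). Hspa5, the chaperone of the endoplasmic reticulum, fell from 5186 ± 1535 to 580.0 ± 161 CPM (-2.88 ± 0.33) with Xbp1, a transcription factor of the unfolded protein response (-2.93 ± 0.35). Herpud1 (adjusted p = 0.0106, and 0.0522 without fresh replicate 4) and the constitutive chaperone Hspa8, named after its value was seen (0.0112, and 0.0738 without fresh replicate 4), also fell. Of 24 autophagy and lysosome genes 8 fell and 2 rose (9 and 3 adjusted over the list alone; camera adjusted p = 0.285), and without scaling factors 3 fell and 3 rose. Map1lc3a, an autophagosome protein, fell from 26.5 ± 4.80 to 0.954 ± 1.04 CPM (-5.02 ± 1.04; adjusted p = 0.0534 with run 2 alone). Also lower were the kinase gene Ulk2 (-2.63 ± 0.72; adjusted p = 0.0268, and 0.0621 to 0.173 without fresh replicates 4 and 5 and cultured replicate 3 in turn), Gabarap (-1.46 ± 0.43; 0.0363, and 0.0621 to 0.216 without fresh replicates 2, 4 and 5 and cultured replicates 1 and 2 in turn) and the lysosomal gene Lamp2 (-1.40 ± 0.34; 0.0153, and 0.0824 without fresh replicate 4 and 0.0599 without fresh replicate 5). Lamp2 stood at -0.04 against run-1 fresh libraries (adjusted p = 0.946), and with run 2 alone the adjusted p was 0.0940 for Ulk2 and 0.103 for Gabarap. The lysosomal genes Lamp1 (adjusted p = 0.0321, and 0.0502 to 0.146 without fresh replicates 4 and 5 and cultured replicates 2 and 3 in turn) and Ctsd (0.0212, and 0.0531 to 0.149 without fresh replicates 4 and 5 and cultured replicate 3 in turn) rose and were named after their values were seen. Of 13 hypoxia genes 3 fell and 1 rose (3 and 2 adjusted over the list alone, as without scaling factors; camera adjusted p = 0.756), with the collagen hydroxylases P4ha2 (-3.48 ± 0.38) and P4ha1 (-1.78 ± 0.27) and the stress gene Ndrg1 (-2.71 ± 0.65; adjusted p = 0.0672 without fresh replicate 4) lower. Vegfa, the vascular growth factor, was higher at an adjusted p of 0.0429, and 0.0579 to 0.175 without fresh replicates 1, 2, 3, 4 and 5 in turn. Of 20 interferon response genes 8 fell (10 adjusted over the list alone) and none rose, among them Oasl2 (34.4 ± 6.59 to 0.136 ± 0.235 CPM; -8.06 ± 1.21), and the camera adjusted p was 0.000603. The interferon list had an adjusted p = 0.0816 with an estimated correlation. Map1lc3a had a log2 fold change of -4.41 without cultured replicate 1 and -6.26 without cultured replicate 3, Ulk2 of -3.55 without cultured replicate 2, and Ndrg1 of -3.82 without cultured replicate 1. Oasl2 had a log2 fold change of -7.45 without cultured replicate 1 and -7.47 without cultured replicate 2. Cultured cells kept no count of Oasl2 without cultured replicate 3. Herpud1 and Ndrg1 lost the call with run 2 alone, and Ulk2 against run-1 fresh libraries (-1.83), with the replicate block and without scaling factors. Gabarap lost the call without scaling factors, and Lamp2 with no run term (-0.77), with the replicate block (-0.05) and without scaling factors. Lamp1 lost the call against run-1 fresh libraries, with the replicate block, with GC and length trends removed, with run 2 alone and with no filter, and Ctsd with no run term, against run-1 fresh libraries, with the replicate block and with run 2 alone. Vegfa lost the call against run-1 fresh libraries, with the replicate block, with run 2 alone and with limma-voom.

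Extracellular matrix genes fell, 22 of 29 lower and 2 higher, or 23 and 2 adjusted over the list alone. Col6a1 fell by 8.39 ± 1.23 on the log2 scale. The laminin gene Lama4 was at 39.8 ± 21.1 CPM in fresh cells and 0 in culture, at least 635-fold lower, and Col15a1 at 120.2 ± 57.1 and 0.0172 ± 0.0297 CPM, a ratio of 9772 (counting interval 1753 to 386032). Tnc, the matrix glycoprotein tenascin C, rose from 22.9 ± 13.0 to 617 ± 86.2 CPM (5.06 ± 0.76) and Thbs1 by 1.62 ± 0.50 (adjusted p = 0.0422, and 0.0650 to 0.199 without fresh replicates 2, 4 and 5 and cultured replicate 2 in turn), both named after their values were seen. In fresh replicate 1 their log2 ratios were -2.36 and -1.32. In fresh replicate 1, 12 of the 29 genes were at a log2 ratio of -1 or lower to the mean of fresh replicates 2 and 3 (median -0.77). For those of them that fell, loss of other cells' RNA and a fall in the stem cells cannot be told apart. The camera adjusted p was 6.11e-06, with an adjusted p = 0.138 with an estimated correlation. Of 28 cytoskeleton, adhesion and YAP/SRF target genes 7 rose and 5 fell (7 and 6 adjusted over the list alone), with a median of 0.01, a mean of -0.53, with camera pointing up and fry down (camera adjusted p = 0.560). Ankrd1 rose from 119 ± 9.15 to 933 ± 88.4 CPM (2.90 ± 0.22), while Ctgf fell from 388 ± 87.4 to 30.5 ± 7.18 CPM (-3.81 ± 0.31) and the actin gene Acta2 fell by 3.71 ± 0.39 on the log2 scale. Tpm2 (-3.97 ± 0.55) and, named after their values were seen, the calponin genes Cnn3 (-1.93 ± 0.32) and Cnn1, at 0 in culture (adjusted p = 0.0212, and 0.0700 without fresh replicate 4), also fell. In fresh replicate 1 the log2 ratio was -1.12 for Acta2 and -1.73 for the tropomyosin gene Tpm2. Col6a1 had a log2 fold change of -7.75 without cultured replicate 1, -12.58 without cultured replicate 2 and -7.80 without cultured replicate 3. The lower group kept no count of Col15a1 without cultured replicate 2 (at least 2167-fold). Thbs1 lost the call with the replicate block and with limma-voom, and Cnn1 with the replicate block.

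Markers of other cells were measured beside these groups. Of 63 marker genes tested 35 were lower in culture and none higher by edgeR, and 23 of the 35 had a fresh mean of at least 10 CPM. Pericyte and smooth muscle genes that were lower included, besides Abcc9 and Rgs5, Pdgfrb (94.6 ± 60.2 to 0.136 ± 0.235 CPM; -9.11 ± 1.29) and Kcnj8, at 0 in culture and at least 869-fold lower, with 7 of 8 lower, also adjusted over the list alone (camera adjusted p = 0.000108, 0.211 with an estimated correlation). Of 8 Schwann and glial genes 7 were lower (8 adjusted over the list alone; camera adjusted p = 0.000323, 0.217 with an estimated correlation). The myelin gene Mbp fell by 6.63 ± 1.27 on the log2 scale. The log2 ratio of fresh replicate 1 to the mean of fresh replicates 2 and 3 had a median of -2.20 over the pericyte, -3.17 over the Schwann, -2.30 over the tendon and -1.11 over the fibro-adipogenic genes. It was -0.84 over the endothelial, -0.28 over the fibre and -0.13 over the immune genes. Of 9 fibro-adipogenic genes 7 were lower, also adjusted over the list alone, including Dpt (297 ± 59.1 to 0.326 ± 0.520 CPM; -10.00 ± 1.03) and Dcn (346 ± 166 to 5.94 ± 2.86 CPM). That list had a median of -6.07 (-5.54 with genes at 0 set to their bounds), a camera adjusted p of 0.000491, and an adjusted p = 0.138 with an estimated correlation. Of 7 endothelial genes 3 were lower (3 lower and 1 higher adjusted over the list alone), which were Tek (-6.01 ± 0.90), Cdh5, with a ratio of 419 (counting interval 143 to 2039), and Vwf (adjusted p = 0.0160, and 0.107 without fresh replicate 5). The higher one was Pecam1, the gene of CD31, at 35.1, 0.103 and 38.1 CPM in cultured replicates 1 to 3. It stood at 4.50, 2.67, 4.32, 0.884 and 0.195 CPM in fresh replicates 1 to 5. Of 7 immune genes 3 were lower, Csf1r (adjusted p = 0.0175, and 0.0644 without fresh replicate 4), Cd79a (0.0159, and 0.0544 without fresh replicate 5) and Lyz2, with Lyz2 at 39.1 ± 21.2 CPM in fresh cells and 0 in culture, at least 1027-fold lower. Of 7 tendon genes 4 were lower, Fmod (-7.29 ± 1.502), Kera and Tnmd, both at 0 in culture and at least 75.1 and 41.6-fold lower, and Thbs4 (adjusted p = 0.0411, and 0.0638 to 0.136 without fresh replicates 2, 4 and 5 and cultured replicates 1 and 2 in turn). Of 16 muscle fibre genes 4 were lower (3 lower and 2 higher without scaling factors), with Myh2 at 0 in culture and at least 56.5-fold lower. The others were Myh1 (adjusted p = 0.0421, and 0.0501 to 0.127 without fresh replicates 1, 2, 3, 4 and 5 and cultured replicate 2 in turn), Pvalb (0.0225, and 0.0601 to 0.248 without fresh replicates 1, 2, 3 and 4 and cultured replicates 1 and 2 in turn) and Atp2a1 (0.0271, and 0.0596 to 0.129 without fresh replicates 2, 4 and 5 in turn). Members of these 4 lists other than Tek, Cdh5, Lyz2, Fmod and Thbs4 were named after their values were seen. Counts adjusted over the list alone were the same in the immune, tendon and fibre lists. The titin gene Ttn (88.1 ± 12.9 and 131 ± 41.0 CPM; adjusted p = 0.143) and the actin gene Acta1 (4.84 ± 2.06 and 27.8 ± 29.1 CPM; adjusted p = 0.0637) did not pass. Without scaling factors both were higher (adjusted p = 0.0196 and 0.0387), and Acta1 also with DESeq2 (0.00612), with no run term (0.0214) and without cultured replicate 3 (0.0254). Camera adjusted p was 0.120 for the endothelial, 0.523 for the immune, 0.120 for the tendon and 0.254 for the fibre list. The red blood cell gene Alas2 was the only tested member of its list and did not pass (adjusted p = 0.622). In total camera called 18 of 35 lists, 9 in each direction, and 6 with an estimated correlation, which were the mitotic, DNA replication, serine, antioxidant, quiescence and immediate early lists. Pdgfrb had a log2 fold change of -8.50 without cultured replicate 1 and -8.52 without cultured replicate 2, Mbp of -6.03 without cultured replicate 1 and -8.60 without cultured replicate 2, and Dpt of -13.32 without cultured replicate 2 and -9.38 without cultured replicate 3. Tek had a log2 fold change of -7.75 without cultured replicate 3, and Fmod of -6.67 without cultured replicate 1, -6.68 without cultured replicate 2 and -6.60 without fresh replicate 5. Cultured cells kept no count of Pdgfrb and Fmod without cultured replicate 3. The bound was 34.03 without fresh replicate 4 and 115 without fresh replicate 5 for Kera, and 99.6 without fresh replicate 4 and 14.7 without fresh replicate 5 for Myh2. The ratio was 189 without fresh replicate 4 and 643 without fresh replicate 5 for Cdh5. The lower group kept no count of Cdh5 without cultured replicate 2 (at least 279-fold). Csf1r, Cd79a, Kera, Tnmd and Pvalb lost the call with the replicate block, and Thbs4 without scaling factors, with run 2 alone and with limma-voom. Myh2 lost the call with the replicate block and with run 2 alone, and Myh1 against run-1 fresh libraries (-4.35), with the replicate block (-6.53), without scaling factors, with GC and length trends removed and with run 2 alone. Atp2a1 lost the call with the replicate block, with run 2 alone and with no filter.

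**Figure D3:**
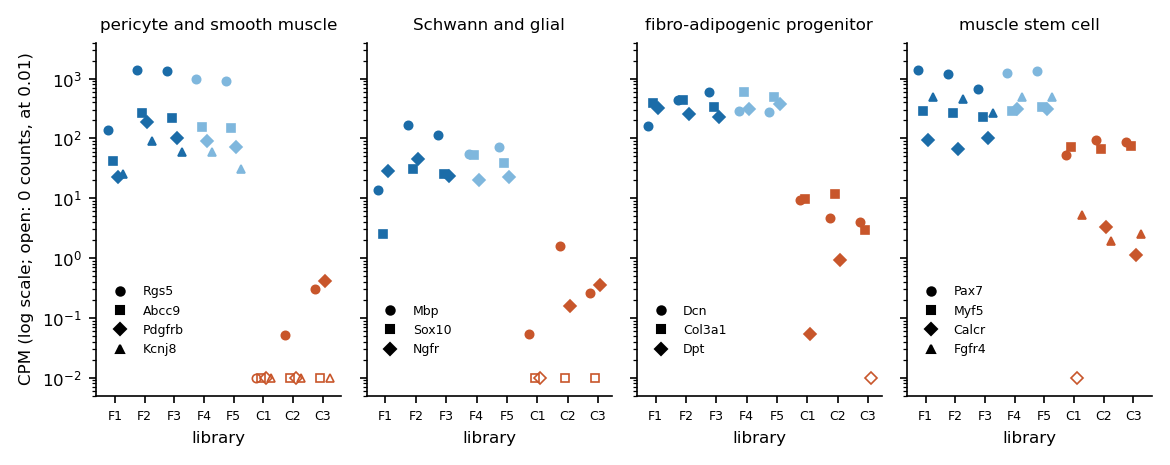
Expression (CPM, log axis) in each library of marker genes of pericytes and smooth muscle, Schwann cells, fibro-adipogenic progenitors and muscle stem cells, with fresh run-1 libraries in dark blue, fresh run-2 libraries in light blue, cultured libraries in orange, and open symbols at 0.01 for 0 counts. Rgs5 averaged 953 CPM in fresh and 0.119 CPM in cultured libraries.

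The comparison of the sequencing runs asked how far fresh libraries of one kind differ between runs. Among named genes, Xist, the RNA that silences an X chromosome, was higher in run 2 (5105 ± 163 CPM, n = 2) than in run 1 (1902 ± 216 CPM, n = 3), a log2 fold change of 1.42 ± 0.20 (adjusted p = 0.0404, edgeR). The mitochondrial mRNA mt-Atp6 went from 100.1 to 1279.6 CPM (3.68 ± 0.54; adjusted p = 0.0477), the cold-inducible RNA-binding protein gene Rbm3 from 82.3 to 262 CPM (1.67 ± 0.24; adjusted p = 0.0447) and the zinc finger gene Zfp292 by 1.49 ± 0.21. Lower in run 2 were Sema7a (3.50 to 0.160 CPM; -4.39 ± 0.50), Lrp8 (2.67 to 0.0967 CPM) and Yam1 (371 to 67.3 CPM). In all 36 genes passed, 18 in each direction, 2959 had an unadjusted p under 0.05, and no member of the fixed gene lists passed. Without scaling factors 10 were higher and 27 lower. The count was 17, 16, 3 and 1 without fresh replicates 1, 2, 4 and 5, and 117 without cultured replicate 1. Each gene named in this comparison had an adjusted p of 0.158 without fresh replicate 4 and 0.143 without fresh replicate 5. Of the 8 genes chosen between runs, 5, 7 and 5 lost the call without fresh replicates 1, 2 and 3. Leaving out cultured replicates 2 and 3 ended 3 and 4 calls, no scaling factors 4, and RLE factors and limma-voom 1 each.

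**Figure D4:**
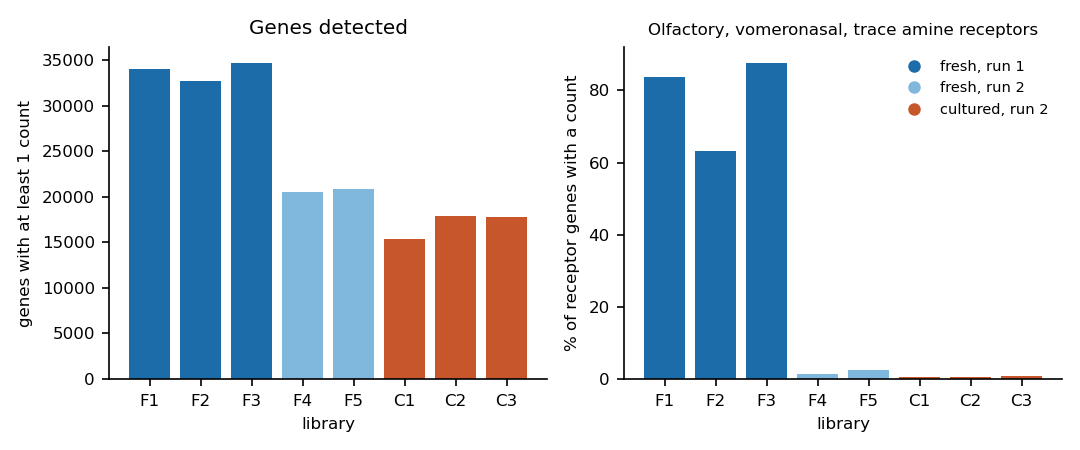
Genes with at least 1 count, and the percentage of 1442 olfactory, vomeronasal and trace amine receptor genes with a count, as bars for each of the 8 libraries. Receptor genes with a count made up 63.1 to 87.7% in the run-1 fresh libraries, 1.53 and 2.43% in the run-2 fresh libraries and 0.485 to 0.902% in the cultured ones.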

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

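The tests of run-1 background, of low counts behind the markers, of depth and of silent genes were chosen only after the result was seen. In 13 of 218 values checked over the 5 fresh libraries (5.96%), 1 library stood apart from the other 4 by Dixon's criterion, which chance alone gives in about 1 in 20.

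Pax7 was at 669 CPM in fresh replicate 3 against 1203 to 1362 CPM in the others, and Fgfr4 at 270.1 against 446 to 494 CPM in the same library, where Pdk4 was at 256 against 124 to 154 CPM. Cd34 was at 124 CPM in fresh replicate 4 against 253 to 283 CPM, Oasl2 at 46.0 against 29.9 to 33.1 CPM, and Asns at 0 against 2.76 to 3.82 CPM. In fresh replicate 2, Notch3 was at 537 against 319 to 368 CPM, Cdk1 at 2.67 against 0.0632 to 0.780 CPM, and Phgdh at 2.60 against 0.900 to 1.07 CPM. In fresh replicate 1, Fdps was at 38.8 against 12.3 to 17.3 CPM and Tpm2 at 26.3 against 76.4 to 91.7 CPM. In fresh replicate 5, Ulk2 was at 96.6 against 38.1 to 53.7 CPM and Acta1 at 1.24 against 5.24 to 6.27 CPM.

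Markers of pericytes, smooth muscle and Schwann cells were lower in culture and uneven among fresh libraries, with Rgs5 at 140.1, 1391, 1352, 975 and 908 CPM in fresh replicates 1 to 5 and the Schwann cell gene Mbp at 13.7, 169.8, 113, 54.6 and 72.6 CPM. Low counts in culture are argued against as the cause, since 23 of the 35 markers called lower had a fresh mean of at least 10 CPM. Over 38 smooth muscle, pericyte and glial genes of a second list, the median log2 ratio of fresh replicate 1 to replicates 2 and 3 was -2.31, against 0.18 over 19 core genes of muscle stem cells. This sets 1 library against 2 and gives no spread between samples. RNA of other cells in the fresh sorts and a fall of these transcripts in the stem cells themselves therefore cannot be told apart. The sort kept cells with α7-integrin and CD34, and left cells out by proteins of blood, fibro-adipogenic and endothelial cells. Whether it removed pericytes and Schwann cells was not tested.

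More genes fell than rose in culture, 67.0% of the calls. Without scaling factors 53.8% of the calls were lower, so the size of the excess depends on the scaling. Over all settings the value lay between 52.8% (a mean of at least 10 CPM) and 74.3% (against a log2 fold change of 1). After removal of a trend with GC content and transcript length, 68.3% were lower (exact 95% interval 67.1 to 69.6). That trend was estimated on the more abundant genes and extended to the rest. The value argues only against a trend shared with the abundant genes as the whole cause. The excess lay in calls under 10 CPM, so a trend particular to those genes could not be tested in this way. The 63.6% lower with the run-2 libraries alone (61.7 to 65.4) says nothing of background reads in run 1, since run-1 libraries have no weight in any culture fold change. Among calls with a mean of at least 10 CPM 50.1% were lower (48.3 to 51.9), against 89.8% of calls under 10 CPM. That value lies between the bounds set in advance, so transcripts missed at low counts in culture and a true fall of rare transcripts cannot be told apart, and an effect of culture itself stays open there.

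The run-1 fresh libraries had counts for more genes than the run-2 fresh libraries. Depth is argued against, since libraries thinned to 11326151 counts outside mitochondrial and ribosomal RNA genes had 33201, 32673 and 34120 genes in run 1 and 20135 and 20639 in run 2, and the lowest run-1 value exceeded the highest run-2 value by 12034 genes. The lowest run-1 percentage of olfactory, vomeronasal and trace amine receptor genes with a count, 63.1%, was 26 times the highest run-2 value, 2.43%. Reads spread over silent genes may therefore be a source of the surplus. Where such reads came from was not tested, and no biological explanation was tested, since both sets were fresh cells.

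All cultured libraries were in run 2, so only 10 splits of the 8 libraries into 5 and 3 leave the runs as they were, too few for a share under 0.05. Among these 10 the real split called 5122 genes and the highest other 1, and 18 gene lists against a highest other of 19. Splits that set fresh replicates 4 and 5 together with 1 cultured library called 16, 18 and 19 lists. Such splits hold much of the real contrast with its sign reversed. Splits that parted fresh replicates 4 and 5 called 0 to 3 lists. The other 45 splits that could be fitted with the run term move the groups across runs. Over all 55, 1 split, the real one, called as many genes (highest other 1) and 11 called as many lists (highest other 20). Some of these also keep the real contrast within run 2, such as fresh replicates 2, 4 and 5 against the rest (20 lists). The list counts of such splits therefore give no chance level. The split by run could be fitted only without the run term, where it called 1260 genes and 14 lists.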

How the results depend on the processing

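Fresh replicate 1 alone as the control, run 2 without cultured replicate 1, and the removal of GC and length trends were chosen after the data were seen. In culture 5122 genes were called, against 3143 with a mean of at least 10 CPM (2905 shared with the main set, fewer genes tested), 2780 with run 2 alone (2725 shared, fewer samples), and 151 against fresh replicate 1 alone (140 shared, 2 opposite, fewer samples, the lone sample assumed to vary like the others). Leaving out each library in turn gave 3337 to 6163, the lowest without fresh replicate 5. Apart from the replicate block below, the other settings stayed within 1.5 times, from 3533 (against a log2 fold change of 1) to 7089 (run-1 fresh libraries as the control, 8 genes opposite).

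With the replicate number as a block and no run term, 2482 genes were called, 2153 of them shared, and the cause was not tested. The sources used here do not say that the numbers pair the samples, so the main test did not take them as pairs. Same-numbered fresh and cultured libraries were sequenced in different runs. Their deviations from the group means correlated at 0.042, -0.0048 and -0.011, and not every library correlated best with its own number. The fresh mean was taken over both runs, so fresh deviations also hold the run difference. For each cultured library, the run-1 fresh libraries correlated with opposite sign to the run-2 ones. These correlations therefore cannot show whether samples were paired.

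Between the runs, 36 genes were called, 81 with no filter on low counts, 62 with a mean of at least 10 CPM, 921 with DESeq2, 1371 with limma-voom and 806 with the 5 fresh libraries alone, and 1 to 117 without 1 library. The cause was not tested. Of the gene lists, 18 were called, 6 with an estimated correlation and 17 to 25 under the others in which camera was run, which left out DESeq2, limma-voom, the test against a log2 fold change of 1 and the removal of trends. Single lists gained a call in 27 combinations of list and setting and lost it in 6, which were the Notch list with run-1 fresh libraries as the control, the block and fresh replicate 1 alone, and the sterol, matrix and fibro-adipogenic lists with fresh replicate 1 alone. The losses against that 1 library, which is of the other run, say nothing of stability.

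Over 209 genes chosen for naming and their settings, 4241 values kept their side of the threshold, 24 of them with no call and a changed sign, 509 lost the call, 171 of them against fresh replicate 1 alone, and 12 gained it. Called genes that changed sign were Lamp2 (log2 fold change -1.40), which was at 0.43 against fresh replicate 1 alone, and mt-Atp6 (-1.67), at 1.19 there, 2.06 with run-1 fresh libraries as the control and 2.13 with the block. Each of these settings rests on run-1 fresh libraries, where mt-Atp6 averaged 100.1 CPM against 1279.6 CPM in run 2 and 402 CPM in culture. Lamp2 was at 139.9 CPM in fresh replicate 1, 484 CPM in run-2 fresh and 183 CPM in cultured libraries. Genes that a setting's filter left out have no value there. Of the called genes, 43 lost the call without fresh replicate 4 and 43 without fresh replicate 5. Leaving out 1 library moved the fold of 78 of 195 called genes by more than 1.5 times, farthest without cultured replicate 1 in 15, cultured replicate 2 in 12, cultured replicate 3 in 22, fresh replicate 4 in 15 and fresh replicate 5 in 14. Of 8 genes chosen between runs, 46 values lost the call and 78 did not. Depth limits what can be said of rare transcripts, since 3 counts over the cultured libraries make 0.0517 CPM.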

Other observations

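Beyond the lists fixed at the start, 5 further lists were written after the main results were known and before they were tested as lists. The genes named from them were chosen after their values were seen. Some members were already known to be lower, such as Kcna2, Kcne4 and Kcnj8 among the channels and Dcn among the imprinted genes. The tests of these lists are therefore not independent of the main results. Noncoding RNAs of the imprinted Dlk1 to Dio3 region fell in culture: Meg3 from 693 ± 176 to 4.31 ± 3.06 CPM (-7.64 ± 0.57; edgeR adjusted p = 0.000132), Rian from 368 ± 161 to 1.83 ± 1.56 CPM (-8.21 ± 0.93) and Mirg to a level 1657 (counting interval 297 to 65502) times lower. Of 24 imprinted genes 13 fell and 1 rose (14 and 2 adjusted over the list alone), the latter Kcnq1ot1, a silencing RNA of another imprinted region (0.82 ± 0.23; adjusted p = 0.0271, and 0.0512 to 0.146 without fresh replicates 4 and 5 and cultured replicate 3 in turn). The hypothesis that imprinted genes were lower as a group passed camera (median -2.32, adjusted p = 8.46e-05, and adjusted p = 0.0516 with an estimated correlation). Of 19 circadian clock genes 10 fell and none rose (13 lower and 1 higher adjusted over the list alone), with Npas2, a partner of the clock's activator, at 73.3 ± 20.9 and 0.154 ± 0.267 CPM (-9.16 ± 1.09) and Rora, a nuclear receptor of the clock, at 323 ± 89.5 and 9.41 ± 4.79 CPM (-5.35 ± 0.52) in fresh and cultured cells. Cry2, a repressor of the clock, fell by 4.30 ± 0.45 on the log2 scale. That list passed in the direction set beforehand (median -2.67, adjusted p = 0.000473, and adjusted p = 0.0516 with an estimated correlation). Meg3 had a log2 fold change of -8.32 without cultured replicate 1, Rian of -8.89 without cultured replicate 3, and Npas2 of -8.54 without cultured replicate 1 and -8.56 without cultured replicate 3. Cultured cells kept no count of Npas2 without cultured replicate 2. The lower group kept no count of Mirg without cultured replicate 3 (at least 365-fold). Kcnq1ot1 lost the call with run 2 alone.

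Translation initiation and elongation factors rose, 14 of 22 higher and 1 lower, or 15 and 1 adjusted over the list alone. Eif2s1, a subunit of the factor that brings initiator tRNA, rose from 43.3 ± 9.33 to 365 ± 63.5 CPM (3.04 ± 0.33), Eif5a from 188 ± 84.9 to 713 ± 66.7 CPM (2.87 ± 0.24) and Eif3b by 2.57 ± 0.42. The elongation factor gene Eef1a1 fell from 4939 ± 368 to 3048 ± 523 CPM (-0.75 ± 0.21; adjusted p = 0.0307, and 0.0568 to 0.155 without fresh replicates 4 and 5 and cultured replicates 2 and 3 in turn). Camera gave an adjusted p = 1.87e-07, and adjusted p = 0.0516 with an estimated correlation. Of 24 voltage-gated and inward-rectifier channel genes 17 fell and 1 rose, or 18 and 1 adjusted over the list alone, with a median of -7.30 (-5.62 with genes at 0 set to their bounds). The sodium channel gene Scn7a stood at 98.6 ± 49.9 and 0.0176 ± 0.0304 CPM, a ratio of 5554 (counting interval 996 to 219445), and Kcnq5 rose from 2.63 ± 1.59 to 21.6 ± 11.2 CPM (4.53 ± 0.85). Scn7a and Kcna2 were low in fresh replicate 1, at log2 ratios of -2.11 and -3.03 to fresh replicates 2 and 3. For such genes, loss of other cells' RNA and a fall in the stem cells cannot be told apart. The list, which holds genes whose fall was known beforehand, passed camera (adjusted p = 6.66e-07, and adjusted p = 0.0516 with an estimated correlation). The hypothesis that mitochondrially encoded mRNAs were higher in culture did not pass (median -0.62, adjusted p = 0.384). Of 13 such genes 2 fell, mt-Co2 (-1.85 ± 0.30; adjusted p = 0.106 with no run term, and -0.12 with adjusted p = 0.765 against run-1 fresh libraries) and mt-Atp6 (adjusted p = 0.0414, and 0.0526 to 0.150 without fresh replicates 4 and 5 and cultured replicates 2 and 3 in turn), and 1 of them fell when adjusted over the list alone. The transcript mt-Atp6 also differed between the runs, and against run-1 fresh libraries it was higher in culture, at 2.06. The lower group kept no count of Scn7a without cultured replicate 1 (at least 1246-fold). Eef1a1 lost the call with the replicate block and without scaling factors, and Kcnq5 with the replicate block (2.38). mt-Co2 lost the call with the replicate block (-0.15), and mt-Atp6 with no run term (-0.51) and without scaling factors.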
